A study of Homo sapiens with 2 samples.

How the data were processed

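RNA-seq counts were analysed for 2 libraries of RKO cells, a human colorectal carcinoma line. One library came from cells transfected with a control siRNA and the other from cells transfected with siRNA against HNRNPM, here called the siHNRNPM library. Groups were taken from the treatment labels, and each column of the table was tied to its library by its title. The values deposited by the authors were whole-number read counts per gene symbol, with no normalization. HISAT2 2.0.4 and the GRCh38 build are listed for these samples, per the submitters' processing notes, without a stated role. The read counter, the gene annotation, the use of strand, the handling of multi-mapped reads, the siRNA sequences and the time after transfection were not given in the sources used here. Reads shared between near-identical copies, overlapping genes and antisense partners could therefore not be assigned with certainty.

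The table held 54261 features, of which 21623 had a read in either library. The siHNRNPM library held 13056118 reads in genes and the control library 19931360. Counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, which gave factors of 1.00 and 0.998, and expressed as CPM, read counts relative to the scaled library size. Genes with a CPM of 1 or more in at least 1 library were kept, which left 12925. The log2 ratio of the siHNRNPM library over the control library was computed per gene, with a count of 0 set to 0.5. Its 95% interval came from the exact Clopper-Pearson interval of the split of the gene's reads between the 2 libraries. These intervals cover counting error only, since reads amplified by PCR are not independent molecules and culture-to-culture variation was not measured. A fold against a library with 0 reads is given against 3 counts in that library, equal to 0.229 CPM in the siHNRNPM library and 0.151 CPM in the control library. Such a fold leaves out counting error, so the limit of the counting interval is given beside it.

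With 1 library per group the differences have no replicate check, and no p-value across genes is given. A gene was counted as at least 2-fold higher or lower when its log2 ratio reached 1 or -1 and its interval excluded a ratio of 1. For each of 39 gene lists the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was described as outside when it lay below the 2.5 or above the 97.5 percentile. These percentiles describe the 2 libraries, not the conditions. HNRNPM was left out of every list, and lists with under 5 measured members were described by their values.

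The design, the lists, the rule for naming genes and all but the later alternatives named at the end were fixed before the data were examined. The rule named HNRNPM and CD44, and every hnRNP family member that passed the 2-fold rule. It named in each direction the 12 protein-coding genes whose interval had its nearest bound farthest from 0, among genes with a CPM of 5 or more in at least 1 library. It named another 5 in each direction by the same ranking among genes with a CPM of 100 or more. From each list it named up to 4 members with the largest absolute log2 ratio whose interval excluded a ratio of 1, or up to 2 for a list inside the central range. Some genes that the rule named are not reported here and were not replaced. Genes named outside this rule are marked as chosen after their values were seen.

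Symbols were matched to a RefSeq gene table, 45971 by symbol and 1854 by synonym, and another 97 by GENCODE name, while 6339 had no match. Biotypes came from the RefSeq table for genes matched by symbol. For the other genes they came from GENCODE where it held the name, and else from the RefSeq synonym. Positions and transcript sequences came from GENCODE release 29 on GRCh38. A gene was recorded as having a copy on an alternate or patch sequence when GENCODE listed transcripts of it outside the primary assembly. For protein-coding genes with no such copy and at least 100 reads over both libraries, the longest annotated 3′ UTR was searched. The presence of each 7-base sequence was regressed on the log2 ratio with 3′ UTR length, GC content and expression in the model, and compared with 100 shuffles of the residuals. The Alu sequence used in 1 check was a consensus written from general knowledge, not taken from the reference.

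The procedure was tested on simulated counts for 12741 genes with the means and depths of these libraries. It recovered 100 of 100 genes changed 3-fold and 100 of 100 changed 6-fold, and it called 44 of 12541 unchanged genes. The interval held the simulated ratio for 12101 of 12741 genes. The simulated counts had counting (Poisson) error only, with no variation between cultures, so these rates are not error rates of the real calls. In simulated data for 10016 genes, the search over 7-base sequences returned the planted sequence in both tests. Alternatives covered total-count, DESeq2 1.42.0 and upper-quartile scaling, thinning of the deeper library, filters on CPM, protein-coding genes only, removal of trends on GC content and length, other fold thresholds, a stricter interval rule and a prior count of 5. Later alternatives left out genes with an alternate copy or with GTGAGAA in the 3′ UTR, and redrew the random lists. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Transcript isoforms and splicing were not analysed here, since the counts are per gene.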

Results

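Gene expression was compared between RKO cells transfected with siRNA against HNRNPM and RKO cells transfected with a control siRNA, with 1 RNA-seq library of each and so no replicates. HNRNPM encodes an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein (hnRNP) family that takes part in pre-mRNA splicing. The comparison addresses how the transcriptome of this colorectal carcinoma line differs when HNRNPM is knocked down. The siHNRNPM library held 13056118 reads in 18851 genes and the control library 19931360 reads in 19882 genes. Mitochondrial genes took 4.58% and 4.45% of these reads, and the 10 most abundant genes took 6.06% and 5.80%. Every interval given below is a 95% counting interval and leaves out variation between cultures.

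HNRNPM itself was lower in the siHNRNPM library, at 79.6 CPM (1042 reads) against 144 CPM (2870 reads) in the control library. This was 55.2% of the control level, with an interval from 51.3% to 59.2%, or a log2 ratio of -0.86 (-0.96 to -0.76). The gene is protein-coding and lies on chromosome 19 from 8444767 to 8489114 on the plus strand of GRCh38 (GENCODE 29, ENSG00000099783.11). Among the 4832 genes with a mean CPM of 50 or more, HNRNPM had the 11th lowest ratio, and the central 95% of those genes ran from -0.53 to 0.43. Among all 12925 measured genes its ratio ranked 340th from the lowest, inside their central 95% of -0.87 to 1.03. HNRNPM itself did not pass the 2-fold rule. The direction goes with the label of the library. CD44, a cell-surface glycoprotein gene, had a log2 ratio of -0.18 (-0.23 to -0.12). In the hnRNP family, 6 of 27 measured members were higher, 11 were lower and the intervals of 10 spanned a ratio of 1. None passed the 2-fold rule. HNRNPK, which encodes a poly(C)-binding hnRNP, had a log2 ratio of -0.66 (-0.70 to -0.62). HNRNPR had 0.96 (0.55 to 1.36), from 120 and 94 reads, and also has a copy on an alternate sequence.

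The largest ratios belonged to genes with few or no reads in the control library. STC2, which encodes the secreted glycoprotein stanniocalcin 2, had 398 reads against 0. It was 202-fold higher when 0 reads are taken as 3 counts (counting interval from 163-fold, a log2 ratio of 7.35). The protease inhibitor gene SLPI had 166 reads against 0, 84.1-fold higher by the same rule (interval from 67.6-fold, log2 6.08). Albumin (ALB) had 77 reads against 0, 39.0-fold higher by the same rule (interval from a log2 ratio of 4.95). AFP, encoding alpha-fetoprotein, had 174 reads against 1 (log2 ratio 8.05, 5.55 to 13.36). SLCO4C1, an organic anion transporter gene, had 130 against 1 (7.63, 5.12 to 12.94). SERPINF1 had 543 against 1 (9.69, 7.20 to 14.99), and SERPINA1, encoding alpha-1 antitrypsin, had 177 against 6 (5.49, 4.34 to 6.95). The synphilin-1 gene SNCAIP had a log2 ratio of 2.74 (2.19 to 3.33). CHCHD10, MIF and SLC25A26 had log2 ratios of 3.98, 3.05 and 2.96. Of these genes, SERPINF1, SERPINA1, CHCHD10, MIF and SLC25A26 also have a copy on an alternate or patch sequence of the genome, where reads can be assigned differently.

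In the other direction, CCND1, which encodes cyclin D1, was 2.42-fold lower in the siHNRNPM library, with 1015 against 3724 reads and a log2 ratio of -1.27 (-1.37 to -1.17). Its 3′ UTR holds 2 copies of the sequence GTGAGAA. Across the 1498 searched genes whose 3′ UTR holds that sequence, the median log2 ratio was -0.14, against -0.01 for the 8518 searched genes without it. TRO, encoding trophinin, had 0 reads against 175. It was 38.4-fold lower when 0 reads are taken as 3 counts (counting interval from 30.9-fold lower, a log2 ratio of -4.95). The histone deacetylase gene HDAC4 had a log2 ratio of -2.02 (-2.71 to -1.39), from 24 and 148 reads. KIAA1211 had -1.28 (-1.44 to -1.12) and the xylosyltransferase gene XXYLT1 had -1.61 (-2.15 to -1.11). GGNBP2 (-4.28), NAPRT (-4.63, from 3 and 113 reads, -6.93 to -3.05), DNAJA3 (-2.09), ECH1 (-1.69), ACTN4 (-1.66) and SNTB2 (-1.37) were also lower, and each has a copy on an alternate or patch sequence.

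Among abundant genes, SEMA3A, which encodes a secreted axon guidance protein, was 2.31-fold higher in the siHNRNPM library (log2 ratio 1.21, 1.12 to 1.29). The heme oxygenase gene HMOX1 was 2.19-fold higher (1.13, 1.07 to 1.20). MRFAP1, TFPI and the histidyl-tRNA synthetase gene HARS had log2 ratios of 1.03, 0.96 and 0.98. Lower abundant genes after CCND1 were CSGALNACT2 (-0.93), EMP1 (-0.92) and MCFD2 (-0.86), each with GTGAGAA in its 3′ UTR. The ribosomal protein gene RPL6 had -0.86 (-0.90 to -0.82) and can share reads with its processed pseudogenes, so its value is uncertain.

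In all, 317 genes were at least 2-fold higher in the siHNRNPM library and 193 at least 2-fold lower, of 12925 measured. Protein-coding genes made up 146 and 131 of these. The log2 ratios of all measured genes had a median of -0.01 and quartiles of -0.21 and 0.18, and the interval of 2849 genes lay above a ratio of 1 and that of 3377 below it. The counts depended on the filter and on the fold required, with 602 and 301 without a CPM filter and 66 and 27 when the whole interval had to lie beyond 2-fold.

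**Figure D1:**
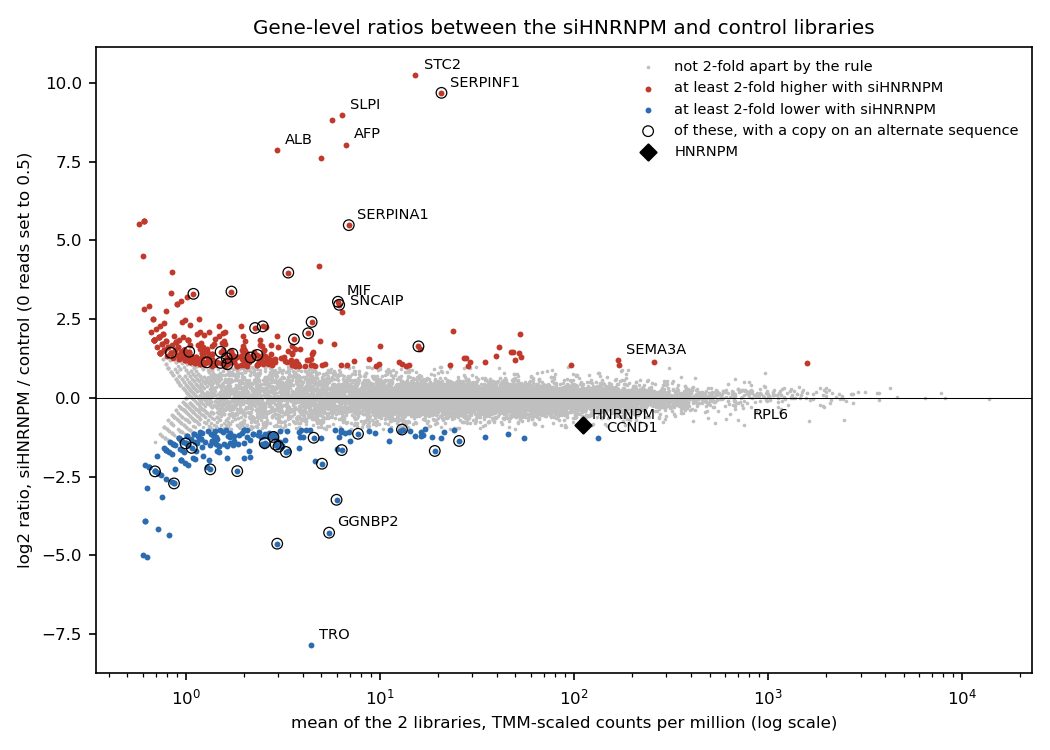
Log2 ratio of the siHNRNPM library over the control library (vertical axis, 0 reads set to 0.5) against mean TMM-scaled CPM of the 2 libraries (horizontal log axis), 1 point per measured gene. Red and blue points are the 317 higher and 193 lower genes, open circles mark those with a copy on an alternate sequence, and the diamond is HNRNPM at -0.86.

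Cholesterol genes were lower together in the siHNRNPM library. Of the 25 measured genes of cholesterol biosynthesis and its regulator SREBP2, 18 were lower, 1 was higher and the intervals of 6 spanned a ratio of 1. The median log2 ratio was -0.29, below that of each of the 10000 matched random lists (central range -0.13 to 0.09). STARD4, a sterol carrier gene with 2 GTGAGAA sites, had -0.76 (-0.83 to -0.70). The exception was PMVK, encoding phosphomevalonate kinase, at 0.78 (0.55 to 1.01).

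The lists of WNT/beta-catenin, TGF-beta/SMAD and YAP/TEAD targets also had lower medians, though the activity of these pathways was not measured. Of 13 measured WNT/beta-catenin targets, 6 were lower, 2 were higher and 5 intervals spanned a ratio of 1, with a median of -0.51 (percentile 0.01). They included CCND1, the pathway antagonist gene NKD1 at -0.95 (-1.22 to -0.68, 3 GTGAGAA sites), PROX1 at -0.70 (-1.07 to -0.33, 1 site) and BMP4 at -1.46 (-2.56 to -0.49, from 11 and 46 reads). Of 16 TGF-beta/SMAD targets, 9 were lower, 2 were higher and 5 spanned, with a median of -0.30 (percentile 0.03). The inhibitory SMAD gene SMAD7 had -1.23 (-1.72 to -0.76), the inhibitor-of-differentiation genes ID1 and ID2 had -1.16 (-1.90 to -0.47) and -0.67 (-1.24 to -0.13), and BMP2 had -3.92 (-9.28 to -1.30), from 1 and 23 reads. Of 18 YAP/TEAD targets, 10 were lower, 5 were higher and 3 spanned, with a median of -0.17 (percentile 1.08). CTGF had -0.80 (-1.06 to -0.54) and PTPN14 -0.48, whereas the tissue factor gene F3 had 0.83 and GADD45A 0.65. Without a CPM filter the YAP/TEAD list no longer lay outside.

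Immediate early genes and interferon-stimulated genes were also lower as lists. Of 25 immediate early and stress genes, 15 were lower, 3 were higher and 7 spanned, with a median of -0.18 (percentile 0.44). FOS had a log2 ratio of -1.05 (-1.36 to -0.75) and EGR1 -0.59 (-0.76 to -0.41), both transcription factor genes. KLF2 and KLF4 had -0.80 and -0.67, each with 1 GTGAGAA site. Of 28 type I interferon-stimulated genes, 9 were lower, 3 were higher and 16 spanned, with a median of -0.17 (percentile 1.46). DDX58, which encodes the RNA sensor RIG-I, had -0.54 (-0.88 to -0.19), DDX60 -0.47, CMPK2 -0.50 and IRF9 -0.78, the last with a copy on an alternate sequence. The interferon list no longer lay outside with upper-quartile scaling, with the control library thinned, with either other CPM filter, with protein-coding genes only, or without genes with an alternate copy.

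Targets of p53 had the highest median of the lists with at least 5 measured members. Of 37 measured, 19 were higher, 4 were lower and 14 spanned, with a median log2 ratio of 0.23 (percentile 100, central range -0.12 to 0.08). The growth-arrest gene GADD45A had 0.65 (0.57 to 0.73), the zinc-finger gene ZMAT3 0.60 (0.52 to 0.68) and the antiproliferative gene BTG2 0.53 (0.34 to 0.71). PLK2 was lower at -1.13 (-2.39 to -0.02), from 9 and 30 reads. Chosen after their values were seen, CDKN1A, which encodes the cell cycle inhibitor p21, had -0.43 (-0.52 to -0.35), and MDM2, the p53 ubiquitin ligase gene, had -0.08 (-0.14 to -0.03) with 1 GTGAGAA site. The list was thus not uniform. Of 35 apoptosis regulators, 16 were higher, 8 were lower and 11 spanned, with a median of 0.10 (percentile 98.4). The anti-apoptotic gene BCL2 had -1.03 (-1.35 to -0.72) and the pro-apoptotic BH3-only gene HRK 1.30 (0.69 to 1.93, from 60 and 37 reads). CYCS, encoding cytochrome c, had 0.79, with 1 GTGAGAA site. The apoptosis list no longer lay outside at a CPM of 5 or more, or without genes that hold GTGAGAA, where its median stayed at 0.10 (27 measured, percentile 95.8).

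Genes of the translation machinery and of oxidative phosphorylation had slightly higher medians. Of 69 cytosolic ribosomal protein genes, 59 were higher, 3 were lower and 7 spanned, with a median of 0.17 (percentile 100). RPS29, RPS21 and RPL11 had 0.43, 0.40 and 0.38, and RPL6 was the exception already given. Many of these genes have pseudogenes that can share reads, which was not tested here. Of 40 MYC targets and ribosome biogenesis genes, 18 were higher, 2 were lower and 20 spanned, with a median of 0.12 (percentile 99.9). The nucleolar gene NOLC1 had 0.77 (0.66 to 0.89), RRS1 0.59 and NOP16 0.55, while the mitochondrial chaperonin gene HSPD1 (1 GTGAGAA site) had -0.51. Of 50 nuclear-encoded subunits of oxidative phosphorylation, 26 were higher, 5 were lower and 19 spanned, with a median of 0.09 (percentile 99.96). NDUFB3, ATP5F1 and NDUFA13 had 0.41, 0.38 and 0.37.

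Stress-response and antigen-presentation genes completed the lists with higher medians. Of 32 ATF4 targets, 12 were higher, 4 were lower and 16 spanned, with a median of 0.11 (percentile 99.4) that does not depend on the value given to STC2. The cystine transporter gene SLC7A11 had 0.47, the pseudokinase gene TRIB3 0.34 and the glycyl-tRNA synthetase gene GARS -0.60. Of 13 antigen presentation genes, 7 were higher, 0 were lower and 6 spanned, with a median of 0.16 (percentile 98.0). ERAP1, CALR, PDIA3 and HLA-F had 0.38, 0.28, 0.23 and 0.53, and HLA-F has a copy on an alternate sequence. Of 26 genes of the unfolded protein response of the endoplasmic reticulum, 11 were higher, 5 were lower and 10 spanned, with a median of 0.09. Its named members were lower in part, with HYOU1 at -1.55 (alternate copy, 20 and 89 reads), ERO1B at -0.76 (1 GTGAGAA site), DNAJB9 at -0.72 and SDF2L1 at 0.41. That list sat at the limit, at percentile 97.6, and lay outside in 10 of 20 further random draws. It lay inside with upper-quartile scaling, with protein-coding genes only, or without genes that hold GTGAGAA, where its median stayed at 0.09 (22 measured, percentile 93.8). The ATF4 list no longer lay outside without a CPM filter or without genes with an alternate copy, and the antigen presentation list without those genes. The antigen presentation list also lay inside without genes that hold GTGAGAA (percentile 96.9), with the same 13 members and median, since only the genes it was compared with changed.

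**Figure D2:**
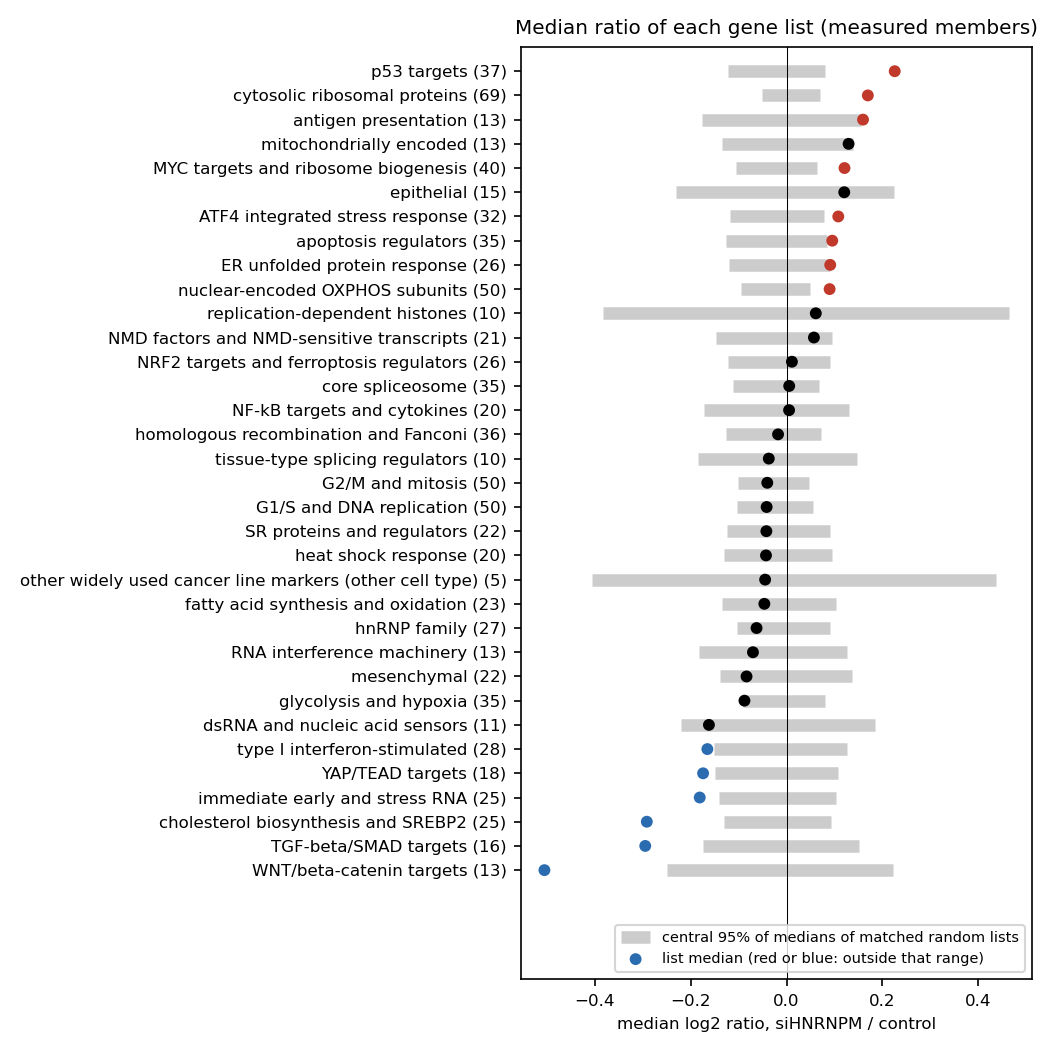
Median log2 ratio, siHNRNPM over control, of each of the 34 gene lists with at least 5 measured members (points, number of members in brackets), with the central 95% of the medians of 10000 matched random lists (grey bars). Red points lay above and blue points below that range, from 0.23 for p53 targets to -0.51 for WNT/beta-catenin targets.

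In total, 14 of the 34 lists with a percentile lay outside the central 95% of random lists, 8 higher and 6 lower. Lists of random genes would give 1.7 on average, but those were drawn gene by gene. Members of a list can vary together between any 2 cultures, and lists share members such as CCND1 and GADD45A. CALR and PDIA3 likewise belong to both the antigen presentation and the unfolded protein response list. The excess over 1.7 is therefore no measure of an effect of the knockdown.

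The other lists with at least 5 measured members lay inside the central range, though 5 of them lay outside it under some other settings, as given with each. Of 35 core spliceosome genes, 11 were higher and 10 lower, with a median of 0.01. PRPF8, encoding a central U5 component, had 1.64 (1.35 to 1.92, alternate copy), and U2AF1, whose sequence has a near-identical copy in GRCh38, had 1.15 (0.56 to 1.76). Of 22 SR proteins and their regulators, 5 were higher and 9 lower (median -0.04), with SRSF8 at 0.97 and SRPK2 at -0.49. Of 10 tissue-type splicing regulators, 4 were higher and 2 lower (-0.04), with ESRP2 at 0.44 and RBFOX2 at 0.23 (alternate copy). Of 21 factors and targets of nonsense-mediated decay, 9 were higher and 4 lower (0.06), including GADD45A and SNHG12 at 0.49. Without genes that hold GTGAGAA, 17 of these remained, with a median of 0.17 that lay outside (percentile 99.7). Among 13 genes of the RNA interference machinery, 1 was higher and 4 lower (-0.07), with AGO2 at -0.72 (1 GTGAGAA site) and DICER1 at -0.44. Of 11 sensors of double-stranded RNA and other nucleic acids, 2 were higher and 5 lower (-0.16), with OAS3 at -0.39.

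Cell cycle genes were little shifted as lists. Of 50 G1/S and replication genes, 12 were higher and 16 lower (median -0.04), with CCND1 lower and the replication gene GINS1 at 0.57. Of 50 G2/M genes, 6 were higher and 16 lower (-0.04), with the centromere histone gene CENPA at 1.14 (0.95 to 1.34) and HMMR at 0.41. Of 36 homologous recombination and Fanconi genes, 7 were higher and 8 lower (-0.02), with XRCC2 at 0.46 and FANCC at -0.52 (1 GTGAGAA site). Of 10 measured replication-dependent histone genes, 1 was higher and 3 lower (0.06), with HIST1H2BD at 1.63 and HIST1H2AE at -1.50, from at most 59 reads. Epithelial genes (15 measured, 6 higher, 3 lower, median 0.12) included the desmosomal gene DSP at 1.34 (1.17 to 1.51) and CLDN3 at 1.51 (0.18 to 2.96, from 15 and 8 reads). The epithelial list lay outside, higher, without genes with an alternate copy (12 measured, median 0.30), at a CPM of 5 or more (10 measured, 0.20) and with the GC and length trend removed (0.23). Mesenchymal genes (22 measured, 6 higher, 7 lower, -0.08) included ACTA2 at 1.95 (1.25 to 2.70) and LOXL2 at 1.66 (0.65 to 2.74), from 61 and 27 reads in the siHNRNPM library, and the list lay outside, lower, at a CPM of 5 or more (17 measured, -0.18).

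Among the remaining metabolic and stress lists, 35 glycolysis and hypoxia genes had a median of -0.09 (6 higher, 21 lower, percentile 3.25), with the glucose transporter gene SLC2A3 at -0.65 and ANKRD37 at -0.62. This list lay outside, lower, at a CPM of 5 or more (-0.10), with the GC and length trend removed (-0.07) and without genes that hold GTGAGAA (-0.11). Of 26 NRF2 targets and ferroptosis regulators, 10 were higher and 7 lower (0.01), with HMOX1 and the thioredoxin reductase gene TXNRD1 (0.59) higher. The 13 mitochondrially encoded genes had a median of 0.13 (10 higher, 2 lower, percentile 96.6), with ND6 at 0.46 and ND1 at 0.42, and lay outside without a CPM filter (percentile 97.8). Of 23 fatty acid genes, 5 were higher and 9 lower (-0.05), with ECI1 at 0.83 and PLIN2 at 0.45. Of 20 heat shock genes, 6 were higher and 9 lower (-0.04), with HSF2 at -0.67 and HSPD1 lower. Of 20 NF-kB targets, 7 were higher and 2 lower (0.01), with TRAF1 at 0.91 and SOD2 at 0.84 (1 GTGAGAA site).

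**Figure D3:**
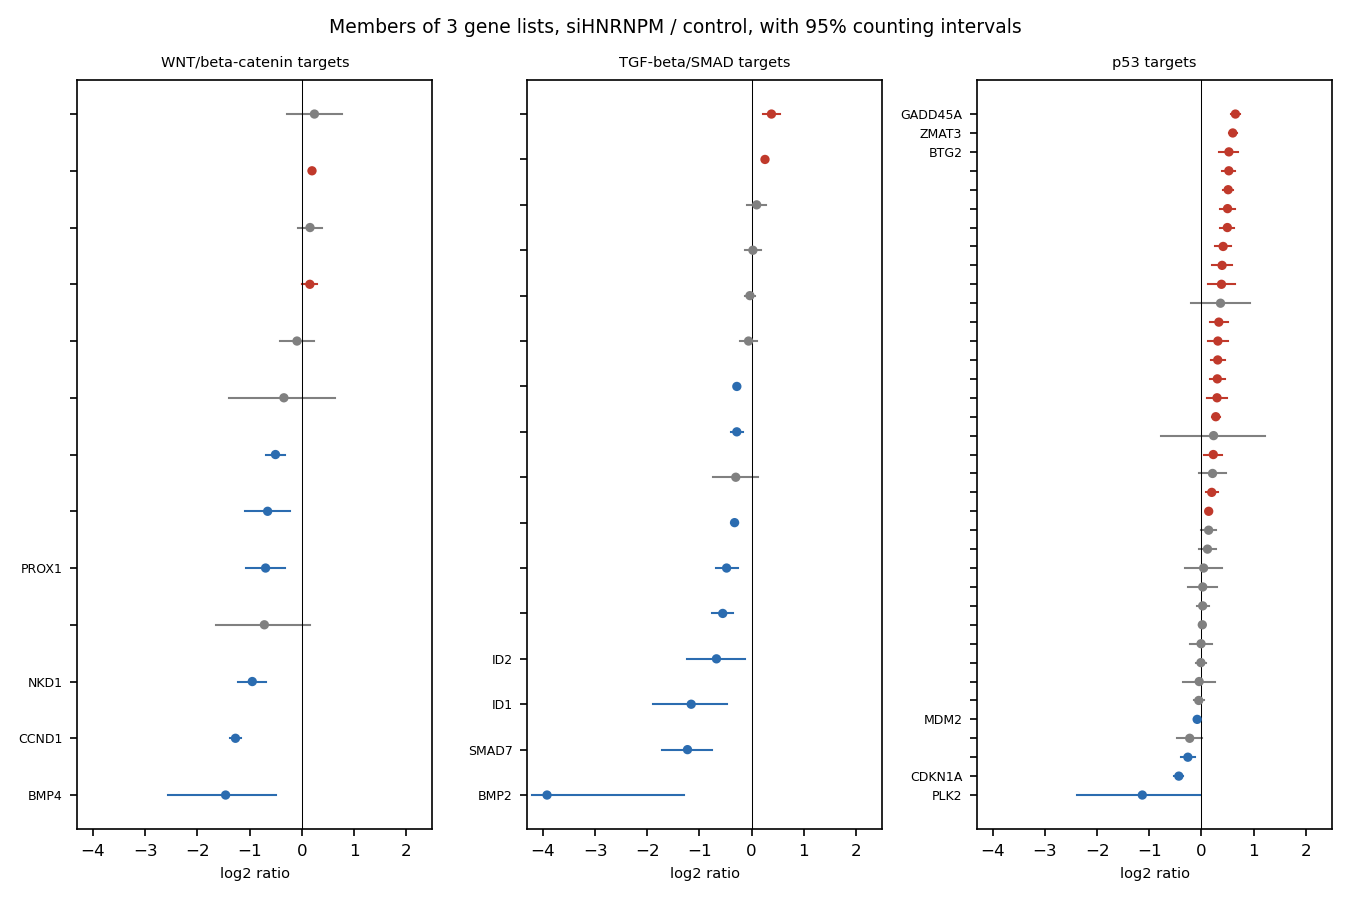
Log2 ratios, siHNRNPM over control (horizontal axes), of each measured member of 3 gene lists (WNT/beta-catenin, TGF-beta/SMAD and p53 targets), the members named in the text being labelled, with lines for 95% counting intervals, drawn red where the interval lies above a ratio of 1, blue where it lies below and grey where it spans 1. The interval of BMP2 runs past the axis to -9.28. BMP4, BMP2 and PLK2 have the lowest ratio of their panels, at -1.46, -3.92 and -1.13.

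Markers of hepatocytes, fibroblasts and endothelial cells gave few reads, and some differed between the libraries. The 12 hepatocyte markers summed to 284 reads in the siHNRNPM library and 14 in the control library, in the former mostly from ALB and SERPINA1, and 10 of them had under 10 reads in both libraries. Fibroblast markers summed to 67 and 48 reads, with COL1A2 at a log2 ratio of 1.41 (0.06 to 2.87) and COL1A1 at 1.30 (0.23 to 2.42), from 14 and 21 reads in the siHNRNPM library. Without a CPM filter, the hepatocyte list (8 measured, 5 at least 2-fold higher, percentile 100) and the fibroblast list (8 measured, 2 at least 2-fold higher, percentile 98.2) lay outside, higher, which rests partly on counts of 0 being set to 0.5. Endothelial markers summed to 35 and 82 reads, with ENG at -1.34 (-2.79 to -0.11). Leukocyte markers summed to 11622 and 15252 reads, mostly from CD68, a lysosomal glycoprotein gene expressed in many cell lines, at 0.21 (0.18 to 0.25). Differentiated colon markers summed to 564 and 1000 reads, with CDX2 at -0.40 and CA2 at -0.19. Markers of other widely used cancer lines summed to 861 and 1285 reads (5 measured, 1 higher, 1 lower, median -0.04), with MITF at -0.54.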

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

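Leaving out genes with an alternate copy, leaving out genes whose 3′ UTR holds GTGAGAA, and redrawing the random lists were chosen only after the data were examined. The HNRNPM log2 ratio stayed between -0.88 and -0.83 in the settings run for it. Against 317 higher and 193 lower genes, dropping the CPM filter gave 602 and 301, a CPM of 5 or more gave 70 and 50, a 1.5-fold threshold gave 646 and 589, a 4-fold threshold gave 55 and 34, and an interval wholly beyond 2-fold gave 66 and 27. These follow from the number of genes admitted by each rule. Protein-coding genes only, 11073 of the 12925 measured, gave 146 higher and 131 lower. The higher share of calls fell from 62.2% to 52.7%, so the genes left out held more of the higher calls than of the measured genes. The other settings stayed within 1.5 times of both counts, and the higher share of calls was 61.4% to 66.3% over the scalings, which shifted the median gene by at most 0.03. The number of lists outside ranged from 12 to 16 against 14, and none of the medians of those 14 lists changed sign in the settings run for medians. The cause of single lists dropping out was not tested. Of the 640 values of named genes under other settings, 631 stayed within their counting interval. The prior count moved 8, to 6.66 for STC2, 6.89 for SERPINF1 and -4.91 for TRO among others, and upper-quartile scaling moved 1. Depth limits genes near 3 counts. No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out.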

Other observations

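The searches over all 7-base sequences were planned before their outcome was seen. The tests on RNA classes, alternate copies, hepatocyte transcripts, the number of libraries, Alu content and lower genes without the sequence were chosen only after the values were seen.

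Long non-coding RNAs were higher as a class in the siHNRNPM library. The 548 measured had a median log2 ratio of 0.19, above the median of each of 1000 random sets matched on expression (central range -0.02 to 0.09), and 78 were at least 2-fold higher against 10 lower. NEAT1, the scaffold RNA of paraspeckles, chosen after its value was seen, was 2.17-fold higher (log2 ratio 1.12, 1.09 to 1.14), from 28330 against 19861 reads. The 664 pseudogenes had a median of 0.06 (percentile 94.4) and the 69 snoRNA genes -0.05 (percentile 13.1). The cause of the shift in long non-coding RNAs was not tested. With the use of strand not given, reads of overlapping or antisense genes could not be assigned with certainty.

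Further genes, chosen after their values were seen, differed at higher read counts. GAP43, a growth cone gene, was 4.39-fold higher (log2 ratio 2.13, 1.88 to 2.39) and ZNF548 4.12-fold higher (2.04, 1.88 to 2.21). The cytokine gene IL11 (-1.25, -1.52 to -0.98), the receptor genes IL10RB (-1.24, -1.44 to -1.04) and TGFBR3 (-1.28, -1.54 to -1.02), and the transcription factor gene ETS1 (-0.80, -0.85 to -0.75) were lower, and each of these 4 holds GTGAGAA in its 3′ UTR. AHNAK, which encodes a large scaffold protein and has no such site, had -0.73 (-0.76 to -0.70).

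Genes lower in the siHNRNPM library carried 4 short sequences in excess of all shuffles. Among 16164 sequences of 7 bases in the 3′ UTRs of 10016 genes, GTGAGAA had a statistic of -12.9 where 100 shuffles reached -4.79, and the next were TGAGAAA at -7.05, TGTGAGA at -6.47 and TGTTTGC at -5.15, the last not a shifted copy of the first. The median log2 ratio was -0.13 with 1 site and -0.23 with 2 or more, and GTGAGAA occurs in HNRNPM itself, in the coding sequence of its longest transcript, exon 15 of 17, at chromosome 19, 8486397 to 8486403 (GRCh38), as do 13.8% of all 7-base sequences. Seed matches of the siHNRNPM duplex lowering off-target transcripts would give this pattern, as a hypothesis only. The siRNA sequence was not given, and other factors that recognise the sequence were not tested. Of the 193 genes at least 2-fold lower, 43 had a searched 3′ UTR, and 17 of these have neither GTGAGAA nor TGAGAA. The hypothesis leaves these 17 unaccounted for, though lacking both is common, at 5137 of all 10016 searched genes. Seed matches of the control duplex stayed open, because 22 of the 25 positive sequences beyond the shuffles lie in an Alu consensus. With Alu content in the model, the highest statistic dropped from 7.19 to 4.94. The shuffles reached 5.16 but were run only without Alu content in the model, so 4.94 and 5.16 are not directly comparable. Before adjustment for 3′ UTR length, genes with the highest of the 25, GGAGAAT, were not higher (median -0.03 against -0.02 without it).

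ALB, AFP, SERPINA1, SERPINF1, STC2, SLPI and SLCO4C1 summed to 1665 reads in the siHNRNPM library and 9 in the control library. Hepatocytes or their RNA are argued against, since APOA1, APOC3, TTR, FGA, FGB and FGG together had 2 reads where ALB had 77, although 5 of the 8 hepatocyte markers measured without a CPM filter were at least 2-fold higher and none lower. Reads shared with copies on alternate sequences are argued against as the cause for the set, since 2 of the 7 genes have such a copy. RNA of another cultured line that expresses these genes without the 6 listed was not tested. The HNRNPM knockdown cannot be told apart from a difference between the cultures, because there was 1 library per group.

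Genes with a copy on an alternate or patch sequence were over-represented among those at least 2-fold apart. Of 315 such genes measured, 44 were called, 23 higher and 21 lower, against a median of 24 and a maximum of 41 in 10000 random sets matched on expression. Their protein-coding members had a median mean CPM of 8.06 against 41.2 for genes without a copy, and PRPF8 lay at 15.8 against a median of 106 for the core spliceosome. Reads shared with the alternate copies may contribute to these calls, though why the libraries would differ in this was not tested. They do not account for the calls as a whole, since 91.4% of the 510 called genes have no such copy.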
